A study of Homo sapiens with 4 samples.

How the data were processed

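RNA-seq of polyA RNA was analysed for 4 libraries of T24 cells, 2 labelled control and 2 labelled IGF2BP3 knockout. Libraries followed the Illumina TruSeq protocol on Trizol-extracted RNA, per the labels' protocols. The authors deposited 1 table per library with an FPKM value (fragments per kilobase of transcript, scaled to the reads of the library) for each of 58302 Ensembl genes, and reads were counted per gene with HTSeq, per the file names. The build was hg38, per the submitters' processing notes. The aligner, its settings, the annotation release, the strand setting and any removal of duplicate reads are not given in the sources used here. Column headers carry the word input, per the file headers, and the series text describes m6A immunoprecipitation sequencing beside RNA-seq, which was not analysed here.

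Depth was worked out from the values. Multiplied by the length of a gene's longest transcript in GENCODE 29, the FPKM of a library were whole multiples of one step, the worth of 1 read, for 96.4 to 96.5% of the genes above 0 (tolerance of 0.0001), and lengths for 513 further genes were solved from the values themselves. The steps gave 2162179, 1870884, 811823 and 1240207 reads as the library totals behind the FPKM of control 1, control 2, knockout 1 and knockout 2, and the recovered reads of all genes summed to 100.5 to 100.7% of that base. Such a length understates expression of genes whose shorter transcripts dominate, and 1 read of a short RNA is worth many FPKM. The median gene above 0 had 92, 62, 47 and 43 reads. Intervals and floors from reads cover counting error only, since reads copied in amplification are not independent molecules. Names, biotypes and positions came from GENCODE 29 (hg38) and matched 58039 of the 58302 genes.

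Genes with a mean FPKM of at least 1 over the 4 libraries were tested, 11463 in all. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend) on log2(FPKM + 0.5), knockout against control with no further term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2(FPKM + 0.5) scale, which understates changes of low genes, and a fitted value for a gene listed at 0 in a whole group depends on the pseudocount and is no bound. Genes that every cell uses were listed at 0 in single libraries, so values are given per library beside the fitted fold changes, which compare group means that include these zeros. Lists of genes (40, of which 33 had at least 5 tested members) were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 33, and 5 of the lists hold markers of other cell types. Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule takes the IGF2BP family, the protein-coding genes past the threshold whose groups do not overlap (up to 12 in each direction), up to 4 leading members of each list described, m6A machinery members past the threshold, and the 3 most abundant genes past the threshold in each direction. A gene named outside it is said to be chosen after its values were seen. One gene the rule takes is not reported here.

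The fits were tested on simulated data built from the mean reads of the real genes and the 4 depths of this comparison, with 200 changed genes. With negative binomial reads (dispersion 0.05), 95.0% of the genes changed by 4 on the log2 scale and 43.4% of those changed by 2 were called among 11349 tested, with 14 false calls among 152. With no changed gene, 10 such simulations called 1 to 15 genes (median 8) among 11340 to 11402 tested. The dispersion was set and not taken from the real libraries, whose median SD between replicates, 1.79 on the log2 scale, was wider. The shares called are therefore no measure of power in the real data. A second simulation drew few molecules read 92.5 times each, a number taken from the spread between the real replicates as if sampling of molecules alone caused it, and there 0 of the changed genes were called at either size among 8768 tested, while a planted list of 30 genes shifted by 1 was called (adjusted p = 9.52e-08) and 0 of 20 random lists were. With no changed gene, it called 0 genes among 8716 tested.

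Alternatives covered the pseudocount, the filter, 3 scalings, the moderation, a replicate block, leaving out each library, the thresholds, the list test and, added after the data were seen, limma-voom on recovered reads, thinning to 817532 reads per library, centring within 20 bins of transcript length and a minimum transcript of 500 nt. A count test was not the main test because the deposited unit is FPKM. Files were joined and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.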

Results

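PolyA RNA of T24, an established human cell line from a bladder (urothelial) carcinoma, was profiled in 4 RNA-seq libraries. Of these, 2 came from cells labelled control and 2 from cells in which IGF2BP3 had been knocked out with CRISPR/Cas9. IGF2BP3 encodes an RNA-binding protein of a 3-member family whose proteins bind messenger RNAs, many of them carrying N6-methyladenosine (m6A). The comparison addresses how gene expression in T24 differs when IGF2BP3 is lost. Whole reads recovered from the deposited values put the libraries at 2162179 and 1870884 gene-assigned reads for the controls and at 811823 and 1240207 for the knockouts, which is shallow for a whole transcriptome. Genes above 0 numbered 8856 and 11433 in the controls and 7827 and 11127 in the knockouts, of 58302 listed. The labels do not say whether the libraries of a group came from separate cultures or clones. The p-values rest on the spread between these samples only, which may be technical. In the limma fit that spread was taken from genes of like level, and a gene's own replicates had no weight in its SE.

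IGF2BP3 RNA was low in both knockout libraries. Its FPKM was 2.94 in control 1 and 21.5 in control 2, against a listed 0 in knockout 1 and 0.190 in knockout 2. These values stand for 27 and 171 recovered reads in the controls, and for 0 and 1 in the knockouts. Scaled for depth, the knockout read total was 0.993% of the control total (exact 95% interval 0.025 to 5.59%, counting error only). This share was 0.533% without control 1, 3.90% without control 2, 1.64% without knockout 1 and 0 without knockout 2. IGF2BP3 (ENSG00000136231) lies on the minus strand of chromosome 7 from 23310209 to 23470467 in hg38. The level goes with the labels, although an edited allele can leave its RNA in place. In the fit over all genes, however, the log2 fold change of −3.89 ± 2.83 (SE, n = 2 and 2), or −2.55 without control 2, did not pass the threshold. Its adjusted p was 0.955 in limma, whose SE here follows the wide spread of genes at that level. Among 1866 other protein-coding genes with a similar control total, 95 (5.09%) had as few knockout reads.

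The paralogs of IGF2BP3 did not pass. IGF2BP1, on chromosome 17, had FPKM of 12.6 and 12.3 in the controls against 19.2 and 14.03 in the knockouts, a log2 fold change of 0.38 ± 1.56 (SE) that lay between 0.16 and 0.60 with 1 library left out. IGF2BP2, on chromosome 3, had 43.4 and 99.3 against 37.4 and 86.8, a log2 fold change of −0.20 ± 0.88 (SE), whose sign turned when control 2 or knockout 1 was left out (0.39 and 0.40). Both differences were smaller than their standard errors.

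**Figure D1:**
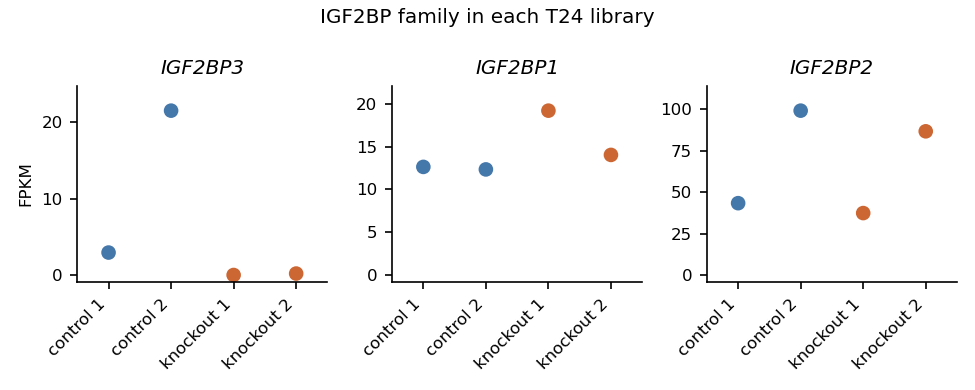
FPKM (linear axis, one scale per gene) of IGF2BP3, IGF2BP1 and IGF2BP2 in each of the 2 control (blue) and 2 knockout (orange) libraries, 1 point per library. IGF2BP3 stands at 2.94 and 21.5 in the controls and at 0 and 0.190 in the knockouts, while IGF2BP1 and IGF2BP2 lie at comparable levels in both groups.

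Few genes separated the groups. Of 11463 genes tested, 10 passed an adjusted p of 0.05 in limma, 7 higher and 3 lower in the knockout, and 3 of them encode proteins. CXCL1, a chemokine that attracts neutrophils, was listed at 0 in both controls and at FPKM 311 and 122 in the knockouts (adjusted p = 0.00792). NDUFB10, a subunit of respiratory complex I, was likewise listed at 0 in both controls and stood at 166 and 121 in the knockouts (adjusted p = 0.0462). H2AC12, a replication-dependent histone H2A gene, had 0 and 221 in the controls against 258 and 254 (adjusted p = 0.00441), so its call rests on control 1, and its fitted log2 fold change of 4.61 was 0.21 without that library and 9.003 without control 2. The remaining calls were noncoding or pseudogene entries, most of them short. SNORD116-6, a small nucleolar RNA of the imprinted chromosome 15 cluster, had FPKM of 0 and 16.7 in the controls against 1437 and 286 in the knockouts. Its fitted log2 fold change of 7.77 ± 1.01 (SE) had the smallest adjusted p of all (1.57e-10 in limma). That SE comes from genes of like level, and the fold lay between 5.22 and 10.3 with 1 library left out. SCARNA7, a guide RNA of Cajal bodies, had 0 and 21.1 against 384 and 112, and RNU5A-1, a U5 spliceosomal RNA gene, had 0 and 23.0 against 244 and 132. Their fitted log2 fold changes of 5.99 and 5.71 were 3.27 and 2.94 without control 1. The ribosomal protein pseudogene RPL39P3 had 0 and 223 against 363 and 140, groups that overlapped, and its fitted log2 fold change of 4.42 was 0.016 without control 1 and 8.82 without control 2.

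On the lower side, RN7SL4P, a copy of the 7SL RNA gene, had FPKM of 1173 and 872 in the controls and 154 and 522 in the knockouts, a log2 fold change of −1.83 ± 0.42 (SE) that was −0.95 without knockout 1 and −2.71 without knockout 2. The processed pseudogene ENSG00000279483 had 857 and 734 against 230 and 204, a log2 fold change of −1.87 ± 0.45 (SE). MIR2278, a microRNA gene, had 520 and 72.4 against a listed 0 in both knockouts. Reads of RN7SL4P, RNU5A-1, H2AC12 and the pseudogenes can be shared with near-identical copies, so these values are uncertain. Sharing of reads was not tested for any call, SNORD116-6 of the chromosome 15 cluster included. Groups did not overlap for 9 of the 10 genes and for 26.5% of all genes tested. Chance gives 33.3% for genes whose values can separate the groups. Over all genes it gives less, since 1447 were above 0 in 1 library only and could not. Leaving out any 1 of control 1, control 2, knockout 1 and knockout 2 ended all 10 calls (0 genes passed, 752 to 1025 at an unadjusted p under 0.05, against 448 with all libraries). The fitted log2 fold change was 7.94 to 9.28 for CXCL1, 7.93 to 8.38 for NDUFB10 and −1.98 to −1.76 for ENSG00000279483 in these fits, which leave 1 library in a group. For CXCL1 and NDUFB10, at 0 in both controls, leaving out a control could not move the fold. Their ranges show only how the knockouts differed, and the size of the fold depends on the pseudocount. Both are among 8 genes at 0 in both controls with at least 50 reads in both knockouts. Pairs of 1 control and 1 knockout library gave 2 to 64 such genes. Of 37 nuclear genes of oxidative phosphorylation, the list that holds NDUFB10, 6 were at 0 in each control. Control 1 with knockout 2 against the rest, a split across the groups, called 9 genes in limma. Transcripts of 8 of the 10 were shorter than 500 nt. Libraries simulated with no changed gene and negative binomial reads gave 1 to 15 calls, 98.6% of them that short. These reads varied less between replicates than the real ones. A simulation of few molecules each read many times gave 0 calls. It also called 0 of the genes changed by 2 or 4, so its 0 decides nothing.

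**Figure D2:**
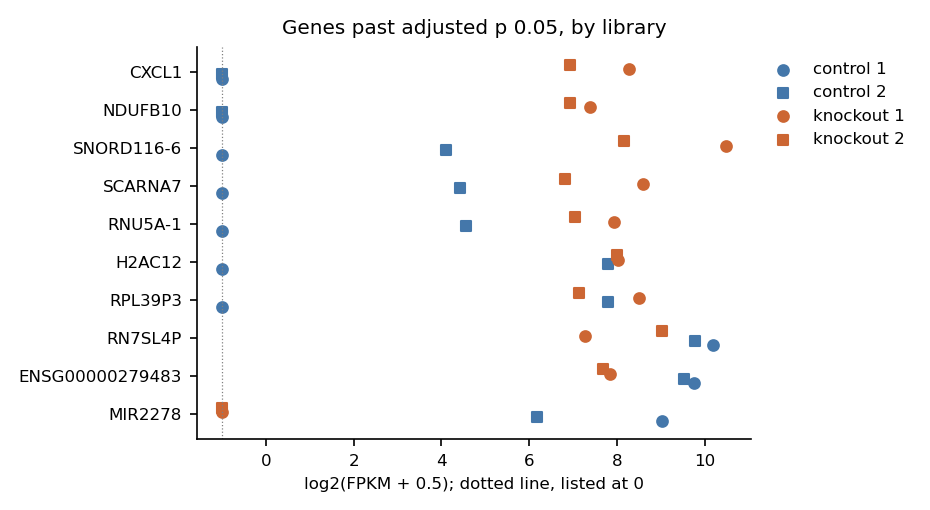
Level of each of the 10 genes past the threshold, as log2(FPKM + 0.5), in the 2 control (blue) and 2 knockout (orange) libraries, 1 point per library, with circles for replicate 1, squares for replicate 2 and a dotted line where a gene is listed at 0. CXCL1 and NDUFB10 are listed at 0 in both controls and MIR2278 in both knockouts, while 5 others called higher are listed at 0 in control 1 alone.

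Among the gene lists fixed before the data were examined, antigen presentation, keratins and replication-dependent histones stood higher in the knockout than other genes. Each passed camera with a preset correlation at an adjusted p of 0.00662, 3 lists of 33 tested, and none passed with an estimated correlation (adjusted p = 0.925 for each of the 3). Antigen presentation genes had the largest shift of the 3, with 11 of 13 members higher and a median log2 fold change of 1.90. No member passed on its own, over all genes or adjusted over the list alone. PSMB8, an immunoproteasome subunit, was listed at 0 in both controls and at FPKM 4.56 and 32.2 in the knockouts. HLA-E had 1.24 and 19.1 against 37.9 and 52.4, HLA-B had 0 and 0.346 against 5.57 and 5.21, and TAP1, a subunit of the peptide transporter, had 0 and 4.70 against 11.2 and 8.72. The call of this list ended without control 2 (adjusted p = 0.0718) and without knockout 1 (adjusted p = 0.170). Of its 13 members, 6 were listed at 0 in some library, and control 1 held the lowest value, alone or tied, for 9.

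For keratins, the intermediate filaments of epithelial cells, 4 of 5 members were higher, with a median of 0.83. KRT8 had FPKM of 266 and 397 in the controls against 1138 and 816 in the knockouts, a log2 fold change of 1.57 ± 0.41 (SE) that missed the threshold over all genes (adjusted p = 0.0896 in limma). KRT18, its partner in simple epithelia, had 173 and 173 against 303 and 314, and KRT7 had 0 and 4.27 against 56.9 and 33.1. KRT80 pointed the other way at 7.60 and 50.4 against 20.9 and 7.66. Adjusted over the list alone, 2 members passed. Without any 1 of the 4 libraries, control 1, control 2, knockout 1 or knockout 2, the adjusted p of the list lay between 0.191 and 0.371.

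Replication-dependent histone genes, whose transcripts mostly lack a polyA tail, were higher for 29 of 45 members, with a median log2 fold change of 0.47, or 0.39 with a member whose controls were all at 0 put at its bound of 3 reads over the group. H2AC12 passed over all genes, and 5 members passed adjusted over the list alone. H4C9 had FPKM of 2.14 and 2.89 in the controls against 112 and 20.6 in the knockouts, H4C12 had 0 and 46.3 against 268 and 20.7, and H2BC9 had 0 and 16.9 against 122 and 10.96. None of these 3 passed over all genes. Control 1 held the lowest value, alone or tied, for 21 of the 45 members, and leaving out any 1 of the 4 libraries ended the call of the list (adjusted p between 0.256 and 0.923).

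NF-kB cytokines and chemokines held CXCL1, the 1 member past the threshold over all genes and over the list alone. Their camera test did not pass (adjusted p = 0.139), with 9 of 13 members higher. CXCL8, a chemokine related to CXCL1, had FPKM of 0 and 0.627 in the controls against 19.5 and 47.3 in the knockouts, and TNFAIP2 had 0 and 0 against 12.4 and 12.7. RELB had 91.3 and 30.5 against 0 and 18.98. None of these 3 passed. The fry test for change in either direction passed for this list (adjusted p = 0.0225) and its test for a shared direction did not (adjusted p = 0.778).

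Small nuclear and nucleolar RNAs that lack a polyA tail included SCARNA7 and RNU5A-1, and 5 of 15 members passed adjusted over the list alone. The list as a whole had 8 members higher and 7 lower, with a median log2 fold change of 0.03 and a mean of 1.05. SCARNA6 had FPKM of 0 and 18.2 in the controls against 37.2 and 183 in the knockouts, and SCARNA5 had 8.38 and 25.2 against 531 and 26.3, neither past the threshold over all genes. The list missed the threshold (adjusted p = 0.051 in camera, and 0.973 with the replicate number as a block).

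No member of the m6A machinery passed. Of 22 members tested, 13 were higher, with a median log2 fold change of 0.19 (camera adjusted p = 0.752). The largest fitted differences were those of YTHDC2, a helicase that binds m6A, at FPKM 0.758 and 3.82 in the controls against 60.6 and 12.02 in the knockouts, and of FMR1 at 0 and 3.54 against 7.14 and 10.9. Literature targets of IGF2BP proteins did not pass either, with 10 of 25 higher (camera adjusted p = 0.914), a median of −0.17 and a mean of 0.37. CCND3, which encodes cyclin D3, had 1.74 and 6.92 against 111 and 32.3, and IGF2, the transcript the family is named after, was listed at 0 in both controls and had 25.4 and 1.30 in the knockouts.

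Proliferation and death genes showed no shared direction. For G1/S genes 15 of 30 were higher (camera adjusted p = 0.891), and for G2/M genes 15 of 29 (adjusted p = 0.824), with no member of either past the threshold. CDC45, a subunit of the replicative helicase, had FPKM of 86.1 and 43.7 in the controls against 0 and 38.2 in the knockouts, and AURKA, a mitotic kinase, had 33.1 and 39.9 against 0 and 50.6, so that its sign turned to 0.47 without knockout 1. Among CDK inhibitors and p53 targets 9 of 20 were higher (adjusted p = 0.752, median −0.03, mean 0.15). CDKN2D had 3.58 and 32.7 against 0 in both knockouts, while CDKN1B, which encodes p27, had 0.348 and 0.201 against 1.85 and 39.8. Apoptosis genes were split 13 to 13 (adjusted p = 0.908). BBC3, which encodes the BH3-only protein PUMA, was listed at 0 in both controls and at 78.4 and 20.6 in the knockouts, and PMAIP1, which encodes NOXA, had 4.75 and 20.03 against 0 and 1.66. None of these genes passed.

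Genes tied to migration and invasion did not pass as groups. Mesenchymal genes were higher for 10 of 13 members (camera adjusted p = 0.332), among them ZEB1, a repressor of epithelial genes, at FPKM 0 and 0.938 in the controls against 33.8 and 2.19 in the knockouts. Extracellular protease genes were higher for 10 of 15 (adjusted p = 0.332). PLAU, the urokinase gene, had 8.35 and 29.2 against 214 and 123, a log2 fold change of 3.33 ± 0.95 (SE), and was the 1 member past the threshold adjusted over the list alone, though not over all genes (adjusted p = 0.182 in limma). CTSL had 0 and 1.47 against 10.2 and 19.3, and ADAM17 had 0.213 and 15.1 against 97.7 and 15.6. Integrin genes were higher for 7 of 12 (adjusted p = 0.923), and ITGB4 had 11.3 and 9.48 against 0 and 3.81.

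Translation and respiration genes did not pass as lists. Small ribosomal subunit genes were higher for 19 of 29 members (camera adjusted p = 0.0846). RPS12 had FPKM of 58.6 and 319 in the controls against 975 and 342 in the knockouts, and was the 1 member past the threshold adjusted over the list alone (adjusted p = 0.0542 over all genes). Nuclear genes of oxidative phosphorylation were higher for 16 of 35 (adjusted p = 0.908), with a median of −0.34 and a mean of 0.11, and NDUFB10 was the 1 member past the threshold. COX6C had 0.421 and 0 against 38.1 and 5.14, without passing.

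**Figure D3:**
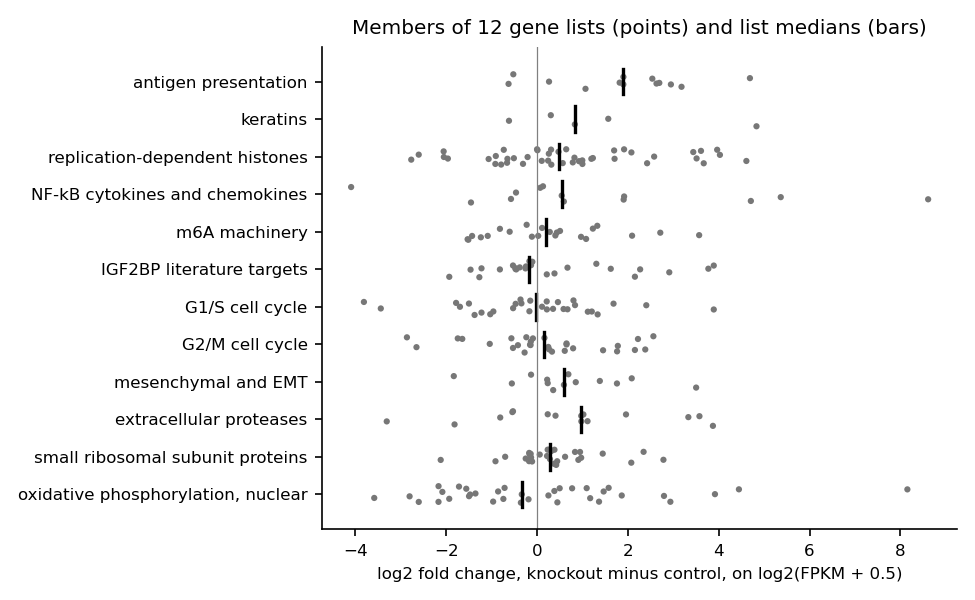
Fitted log2 fold change (knockout minus control, on log2(FPKM + 0.5)) of each tested member of 12 gene lists, 1 point per gene, with a bar at each list's median. The antigen presentation median lies at 1.90, the keratin median at 0.83 and the histone median at 0.47, and members of every list fall on both sides of 0.

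The 4 libraries resembled each other little, within groups as between them. Across the 11463 genes, which are not independent replicates, Pearson's correlation of log2 values was 0.49 between the controls and 0.43 between the knockouts, and 0.42 to 0.49 between libraries of different groups. At least 1 library listed 49.4% of the tested genes at 0, among them genes that every cell uses. TBP, HPRT1 and METTL3, named after their values were seen, were listed at 0 in knockout 1 and stood at FPKM 7.84, 56.7 and 20.5 in knockout 2. In the controls, 1102 genes had at least 50 reads in 1 library and 0 in the other, and in the knockouts 1049 had.

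**Figure D4:**
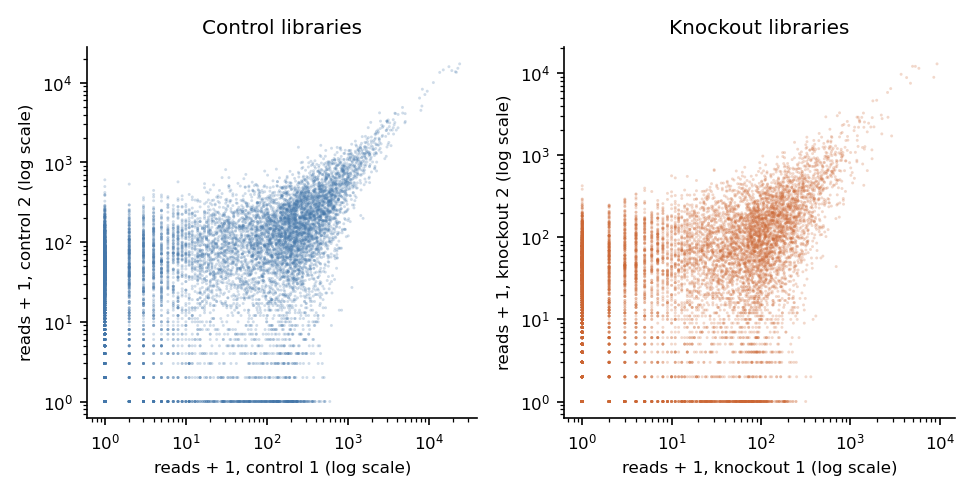
Recovered reads + 1 of each tested gene (log scales) in control 1 against control 2 (left, blue) and in knockout 1 against knockout 2 (right, orange), 1 point per gene. Points along the axes at 1 are genes listed at 0 in one library, at any height in the other, and only the most abundant genes lie close to a line.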

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

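Tests with limma-voom, thinning, length bins and a minimum length were chosen after the data were seen. IGF2BP3 stayed below 0 and short of the threshold in all 16 alternatives that kept the 4 libraries (−5.57 to −3.11) and with each library left out (−5.23 to −2.55). The count of 10 genes stayed between 7 and 14 in 13 of its 23 alternatives. It came to 18 at an adjusted p of 0.1, 2 among protein-coding genes, 1 among transcripts of at least 500 nt (fewer genes tested), 28 after centring within length bins (16 higher, 12 lower), 0 under limma eBayes without trend (415 at an unadjusted p under 0.05) and 0 after thinning (257). Limma-voom gave 10 genes, of which 2 were shared. With each library left out the calls ended in limma, where the lone library of an arm is assumed to vary like the other group. The folds were then 7.94 to 9.28 for CXCL1, 7.93 to 8.38 for NDUFB10 and −1.98 to −1.76 for ENSG00000279483. Leaving out a control could not move those of CXCL1 and NDUFB10, which were at 0 in both controls. The count of 3 lists was 6 under limma-voom, 1 without trend, 0 with an estimated correlation, 0 with fry, and 0 to 3 with a library left out. Antigen presentation passed in 16 of 20 alternatives, keratins in 10 of 19 and histones in 9 of 20. Libraries with the same replicate number shared no deviation (correlation of −0.004 across genes). With 49.4% of the tested genes at 0 in some library, this cannot exclude a pairing, which the labels do not give. The fit with the number as a block gave 14 genes, 3 lists and IGF2BP3 at −3.89. Signs turned for 10 of 60 genes with a library left out: IGF2BP2 (−0.80 to 0.40), KRT80 (−1.95 to 0.71), RPS10 (−1.60 to 6.29), AURKA (−6.20 to 0.47), COL6A1 (−0.53 to 4.70), SOCS4 (−5.14 to 0.50), TBP (−3.98 to 0.080), HPRT1 (−3.05 to 3.79, and −0.31 with a pseudocount of 0.1), METTL3 (−3.78 to 1.61) and PLEC (−0.014 to 0.25). The cause was not tested, except where fewer genes or libraries were used. DESeq2 was not run because the files hold no counts. Depth limits all of these values.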

Other observations

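The tests of read sampling and of recovered reads in the short RNA pattern were chosen only after their results had been seen, as were the limma-voom values. Stress genes did not pass as lists. Of the unfolded protein response and ATF4 genes 19 of 26 were higher (camera adjusted p = 0.520), and of the heat shock genes 12 of 17 (adjusted p = 0.102). Luminal urothelial genes were higher for 7 of 9 members (adjusted p = 0.0846), and 1 member, KRT8, passed adjusted over the list alone. Interferon response genes were higher for 8 of 13 with a median of 0.43, a mean of −0.14 and a camera direction of lower (adjusted p = 0.912). TGF-beta pathway genes were higher for 9 of 24 (adjusted p = 0.891) and WNT pathway genes for 9 of 18 (adjusted p = 0.824). Mitochondrially encoded mRNAs were higher for 9 of 13 (adjusted p = 0.332), while reads from mitochondrial genes made up 0.755% and 0.760% of the control libraries and 1.25% and 0.558% of the knockouts. Markers of 5 other cell types made up at most 0.0451% of the reads of any library, which was fibroblast markers in control 1. Of 14 leukocyte markers 1 had reads, CORO1A, named after its values were seen, with 0 and 15 in the controls against 110 and 13 in the knockouts (log2 fold change of 3.45 ± 2.58, adjusted p = 0.955), and knockout 1 was also a library without which the antigen presentation list no longer passed.

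Limma-voom, which weighs genes by their reads, called 10 genes, and those named here were chosen after their values were seen. KRT8 had the largest change of those detected in all libraries, at 1.51 (adjusted p = 1.80e-09, with 1.80e-09 to 0.891 over its 16 alternatives). FASN, the fatty acid synthase gene, had FPKM of 414 and 402 in the controls against 76.5 and 276 in the knockouts, a log2 fold change of −1.22 (adjusted p = 5.07e-04, with 5.07e-04 to 0.970 over its 16 alternatives). In the limma fit on FPKM the value for FASN was −1.49, and −0.56 without knockout 1 and −2.41 without knockout 2. PLEC passed with a change of 0.06 (adjusted p of 0.00390 to 0.999 over its alternatives, FPKM of 727 and 606 against 756 and 684), although its groups overlapped. The smallest adjusted p in limma-voom were those of RN7SL2 (change of −0.47, 2.03e-22) and MALAT1 (0.22, 2.87e-19). MALAT1 had FPKM of 722 and 829 against 1219 and 823, which overlap. A small adjusted p in limma-voom is thus no sign here that the replicates separate the groups. MRPS6 was listed at 0 in both controls and at 29.1 and 40.4 in the knockouts, as with CXCL1 and NDUFB10 a gene seen in 1 group alone. Genes at 0 in both controls with at least 50 reads in both knockouts numbered 8, and the reverse 29. Pairs of 1 control and 1 knockout library gave 64, 19, 19 and 2 such genes, so the counts along the groups lay within the range of these mixed pairs.

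Many genes had at least 50 reads in one replicate and 0 in the other, and sampling of independent reads is argued against, since their number exceeded the binomial number by 1102 in the controls and by 1049 in the knockouts. Few captured RNA molecules, each read many times, may account for the pattern but stay open, since the variance between replicates over its binomial value should then level off with abundance. From the lowest of 4 read ranges (50 to 200, to 1000, to 5000 and above) to the highest, it stood at 70.6, 101, 101 and 152 in the controls and rose through 52.1, 78.6, 132 and 319 in the knockouts, where the third range was 1.67 times the second. Genes switched off in one culture also stay open. Genes that every cell uses were at 0 in one replicate for 1.75% against 6.67% of matched genes in the controls (lower by 4.91 percentage points) and for 8.93% against 7.93% in the knockouts, shares too low for the difference of 10 points set in advance.

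Short RNAs led the genes called higher in the knockout, 5 of 7 with transcripts shorter than 500 nt against 5.37% of all genes tested. After centring within length bins, the median log2 fold change of the 7 genes kept 94.3% of its value. This argues against a trend of the libraries with transcript length as the source of folds this large. Whether a smaller trend helped genes pass stays undecided, and centring took the count of calls from 10 to 28. The lower depth of the knockouts stays open as a source of the folds. Of the 7 genes, 5 had 0 reads in both controls or at least 3.54 times the highest control reads in each knockout. Their reads were thus higher in the knockouts before any scaling for depth. The genes were called for being higher there, however, so this outcome was largely fixed by the choice. For H2AC12 and RPL39P3 the reads overlapped. Thinning leaves a 0 at 0 and all 7 genes were at 0 in control 1. The 102.8% kept (5.99 before and 6.16 after) therefore decides nothing. The calls ended as the median SE grew from 1.23 to 1.65, with 0 or 1 of them left in each of 20 draws. Short RNA carried by 1 knockout library stays open. The median fold of the 7 genes kept 88.0% without knockout 1 and 114.8% without knockout 2. These genes were called with both knockouts in the fit, so a gene high in 1 knockout alone was unlikely to be among them. Control 1 carried much of the pattern, since all 5 short RNAs were listed at 0 there and 51.4% of their median was kept without it, against 154.3% without control 2. A rise of short RNAs in the knockout stays open as well, since 255 small or structural RNAs had a median log2 fold change of 0.004 against −0.08 for protein-coding genes, with 3 called higher and 2 lower, which decides nothing.

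The count of 10 genes past the threshold may reflect short RNAs that were given too small a spread for their few reads, since the test ties the spread to FPKM and not to reads. For H2AC12 (SE 0.94) and RPL39P3 (SE 0.96) the SE was too small for their own replicates. Their folds ran from 0.21 to 9.003 and from 0.016 to 8.82 with 1 library left out. The same held for SNORD116-6 (SE 1.01, 5.22 to 10.3), the call with the smallest adjusted p in limma. It also held for SCARNA7 (SE 1.23, 3.27 to 8.70), RNU5A-1 (SE 1.26, 2.94 to 8.49) and RN7SL4P (SE 0.42, −2.71 to −0.95). The folds of ENSG00000279483 (SE 0.45, −1.98 to −1.76) and MIR2278 (SE 1.85, −10.02 to −7.19) moved less beside their SE. Whether few reads are the reason stays open. In 10 simulations with no changed gene and negative binomial reads, 98.6% of the 73 calls had transcripts shorter than 500 nt, against 5.16% of the genes tested, and 8 of the 10 real calls were that short. A simulation of few molecules each read many times called 0 of 8716 genes. That 0 decides nothing, since this simulation also called 0 of the genes changed by 2 or 4. The negative binomial reads varied less between replicates than the real ones, whose median SD was 1.79 on the log2 scale. The simulation of few molecules was not shown to match that spread, and it left 8716 genes to test against 11463. Of the 3 splits of the 4 libraries into pairs, 1 gave as many genes as the real one, which was the real split itself with 10, and the highest of the others gave 9. At an unadjusted p under 0.05 the real split gave the fewest genes, 448 against 606 and 452, and with 3 splits no share under 0.05 can be reached. CXCL1 and NDUFB10 are the 2 calls with longer transcripts, and of these CXCL1 passed in 13 of 16 alternatives that kept the 4 libraries and NDUFB10 in 7 of 16.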
